A study of Mus musculus with 30 samples.

How the data were processed

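ATAC-seq libraries of cultured mouse splenic NK cells were analysed, 30 in all, in 8 groups made by genotype (C57BL/6J, or GzmbCre with Ptger2 and Ptger4 targeted alleles), PGE2 (0 or 100 ng/ml) and NK1.1 stimulation. Per the labels' protocols, cells were cultured for 5 days with IL-2 and IL15:IL15Ra, treated for 5 h, and in the stimulated groups given NK1.1 stimulation for the last 4 h after 1 h of treatment. The labels number replicates from 1 to 4 within a group. They do not say that replicates came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical. Conditioned medium, named in the series description, was not among the samples analysed here.

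Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.39, aligned to mm10 with Bowtie2 2.4.1, and peaks were called with MACS2 2.2.7.1 and normalised with DESeq2, whose version is not given in the sources used here. The handling of duplicate reads and of the transposase offset is not given in the sources used here either. The deposited table holds, as signal per peak and library, read counts divided by a size factor per library, per the file headers and the submitters' processing notes. It lists 38526 peaks shared by all libraries, with coordinates, a gene and a class per peak. Introns held 12700 peaks (33%), promoters 12048 (31.3%), intergenic sequence 10483 (27.2%) and exons 3295 (8.6%), the peaks were 237 to 5682 bp wide, and 14886 genes were named. Coordinates were read as 1-based with the end included, since the given width was the end minus the start plus 1 in all 38526 peaks. Gene assignments are those of the table, which measures accessibility near a gene, not its expression. Of 14768 gene identifiers in the table, 14755 were found in the reference table of assembly GRCm38.p6.

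Whole reads were recovered from the deposited values. In every library 100% of values came out as whole multiples of the value of 1 read, within a tolerance of 0.05, with a largest deviation of 0.0228. The value of 1 read ranged from 0.6628 to 1.6644 normalised counts, and reads in peaks from 8444350 to 20153816 per library. At this depth 112 of all values were 0, at most 26 peaks in a library. Intervals and floors given for low peaks cover counting error only, since PCR reads are not independent molecules. For a group with 0 reads, a bound was computed against a floor of 3 reads over the group.

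The main test was limma on log2(normalised count + 1), with trend and empirical Bayes moderation, 1 mean per group over all 30 libraries, no replicate block, and two-sided tests. Peaks with a mean of at least 10 entered, which left 38525 and removed 1. A peak was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. The comparisons were PGE2 against untreated in each genotype and stimulation state, stimulation in each genotype, the KO against WT in untreated resting cells, and 4 interactions. Genotype interactions are coded as the effect in WT minus that in the KO, and the interaction of PGE2 with stimulation as the effect with NK1.1 minus that without. The KO against WT in the other 3 conditions was added later.

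The groups, the main tests, the gene lists and the naming rule were chosen before the data were examined. The rule named, per comparison, the 8 largest positive and 8 largest negative log2 changes among called peaks with a mean of at least 50 in the higher group and no overlap between libraries, with 1 peak per gene. It also named up to 4 genes per list by the smallest p, and every peak of Ptger2, Ptger4, Ifng, Ccl5, Xcl1, Crem, Nr4a1 and Gzmb. Interactions at these peaks are given where the genotypes are compared. Gene assignment was treated as uncertain in families of similar genes and in genes named Gm with a number. Among these families were Klra to Klre, Klri, Gzm, Ccl, Serpinb9, Gimap, Ifit and Oas. Peaks outside the rule, named after their values were seen, are the 3 of the interaction of genotype and stimulation and the examples among the other observations.

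The 18 lists were cAMP and CREB targets, NK cytokines and chemokines, cytotoxic granule genes, NK receptors, receptor activation genes (NFAT, NF-κB and AP-1), IL-2, IL-15 and STAT5 genes, interferon-stimulated genes, NK transcription factors, prostanoid and other Gs-coupled receptors, TGF-β and tissue residency genes, migration genes, glycolysis and mTOR genes, housekeeping genes, and markers of B cells, T cells, myeloid cells, erythroid cells, and ILC2 and ILC3 cells. All peaks of a list's genes were tested with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over lists within a comparison. Peak sets called in one comparison were read in others that share no library with it, as shares of the same sign and with camera. Set means per library were compared with exact permutation tests, two-sided and adjusted over all set comparisons, also those that had called a set, and peak classes with Fisher's exact test.

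The fit was tested on simulated data for 38525 peaks, with 200 changed peaks, 50 per fold, chosen above a minimum level. Counts were drawn independently per library from negative binomial distributions, with group means and dispersions estimated from the real libraries. Differences by replicate number were thus absent. With 200 changed peaks the adjusted threshold is stricter than where far more peaks change, so the recovered shares do not carry over to such comparisons. For PGE2 in resting WT, 48%, 96% and 100% of peaks changed 1.5-fold, 2-fold and 4-fold were recovered. The same shares were 52%, 82% and 100% for PGE2 in resting KO, 50%, 84% and 100% for PGE2 in stimulated KO, and 54%, 92% and 100% for the genotypes. Of the smallest simulated change, 8%, 8%, 12% and 8% were recovered. Calls on unchanged peaks made up 11.9%, 8.33%, 7.52% and 8.63% of all calls in these 4 simulations, above the nominal 5%.

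Alternatives were total-sum scaling, quantile normalization, a pseudocount of 5, no filter, a stricter threshold of 0.01 for the peak sets, an added minimum of 1 for the log2 change, only the libraries compared, a replicate block, each library left out in turn, and edgeR and DESeq2 on the recovered reads. On those reads edgeR called 5911 and DESeq2 6311 peaks for PGE2 in resting WT. Analyses of the libraries numbered 1 and 2 or 3 and 4, a term for these number groups, promoter peaks only, and omission of chromosomes 14 and 15 were added after the data were seen. The search for sequence motifs was not run, and the column of the table that codes each peak's pattern was not used here. The versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.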

Results

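Chromatin accessibility was measured by ATAC-seq, in which a transposase tags open DNA, in 30 libraries of cultured mouse splenic natural killer (NK) cells. The cells came from C57BL/6J mice (wild type, WT) or from mice whose NK cells lack the prostaglandin E2 (PGE2) receptors EP2, encoded by Ptger2, and EP4, encoded by Ptger4 (EP2/EP4 KO, here the KO). The KO mice carried GzmbCre and the WT mice did not, so a difference between genotypes cannot separate receptor loss from Cre. Cells of each genotype were left untreated or given PGE2 at 100 ng/ml for 5 h, and were left unstimulated or stimulated through the activating receptor NK1.1 for the last 4 h. The 8 groups held 4 libraries each, except unstimulated WT with PGE2 and unstimulated untreated KO, which held 3. Each library held 8444350 to 20153816 reads in 38526 peaks. Values are normalised read counts given as mean ± SD of a group's 3 or 4 libraries, log2 changes carry their standard error, and coordinates are those of mm10.

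The targeted loci separated the genotypes in every library. The Ptger2 promoter peak (chromosome 14:44988181–44990885) lay between 559.8 and 1109 in the 15 WT libraries and between 83.61 and 247.3 in the 15 KO libraries. In untreated unstimulated cells it was 630 ± 56.7 in WT (n = 4) and 113 ± 18.2 in the KO (n = 3), a log2 difference of −2.47 ± 0.12 (limma adjusted p = 8.35e-18). The exon peak of Ptger4 (chromosome 15:5241955–5243110) lay between 433.5 and 685.1 in WT and between 56.24 and 152.3 in the KO, with a difference of −2.74 ± 0.17 (limma adjusted p = 4e-14). The neighbouring Ptger4 promoter peak (chromosome 15:5243535–5244984) was 1050 ± 112 in WT and 1050 ± 90.7 in the KO, and the other 4 Ptger4 peaks were not called. In WT cells the Ptger2 promoter peak rose with NK1.1 stimulation, from 630 ± 56.7 to 1030 ± 80, and was 629 ± 14.4 when PGE2 was present during stimulation, so the receptor's own promoter was among the peaks that PGE2 lowered (−0.71 ± 0.11, limma adjusted p = 1.4e-06).

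The first principal component, with 67.1% of the variance, followed stimulation, and the next, with 9.3%, followed PGE2 in WT cells. Stimulated untreated libraries averaged 86.1 ± 9.4 in WT and 100.4 ± 12.6 in the KO on the first component, against −94 ± 7.6 and −75.7 ± 12.2 without stimulation. Stimulated WT libraries with PGE2 averaged 6.3 ± 2.9, between both states, while stimulated KO libraries with PGE2 averaged 88.6 ± 18.6. On the other component, WT libraries with PGE2 averaged 44.2 ± 1.4 without and 58.5 ± 7.1 with stimulation, and the remaining groups lay between −29.3 and −3.9.

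**Figure D1:**
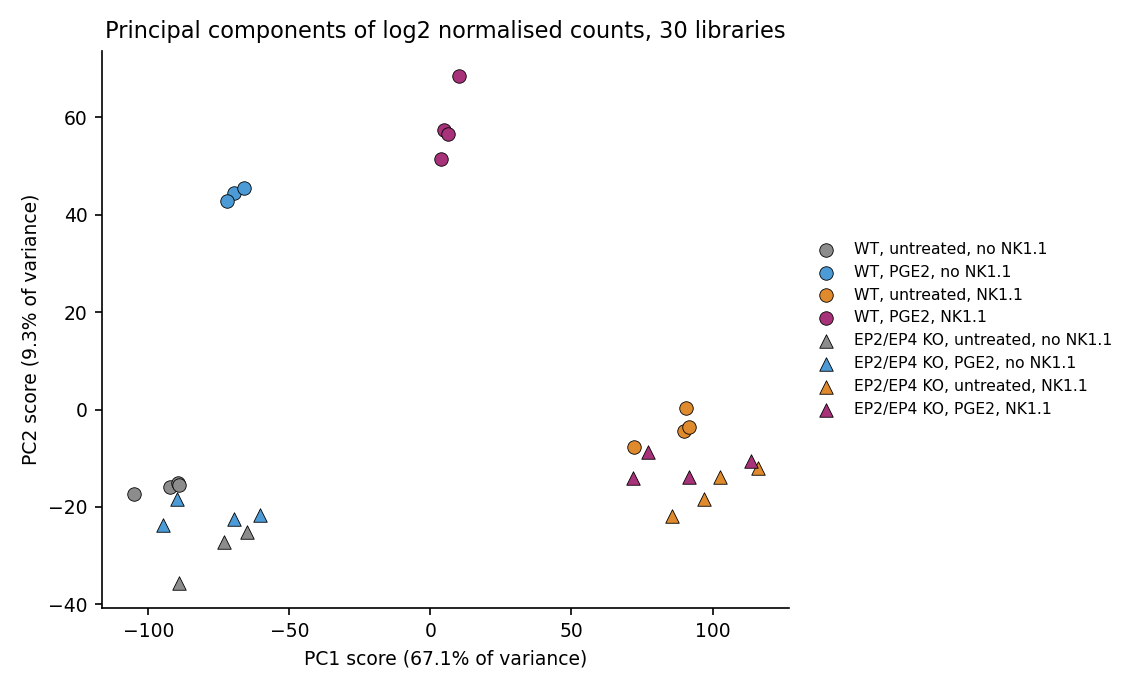
Principal components of log2(normalised count + 1), 1 point per library (circles WT, triangles KO), with the share of variance on each axis. Stimulated WT libraries with PGE2 average 6.3 on the first component, between unstimulated WT (−94) and stimulated WT (86.1).

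In resting WT cells, PGE2 opened single peaks of Pdcd1, Nt5e, Stat3 and of some cAMP target genes. A distal peak of Pdcd1, which encodes the inhibitory receptor PD-1 (chromosome 1:94074313–94075538), rose from 53.6 ± 8.49 to 575 ± 87.7, a log2 change of 3.40 ± 0.24 (limma adjusted p = 2.07e-13). A distal peak of Nt5e, the ectonucleotidase CD73 that makes adenosine (chromosome 9:88276060–88276719), rose from 10.1 ± 2.42 to 76 ± 12.8, and an intronic peak of the transcription factor gene Stat3 (chromosome 11:100933480–100934628) rose from 97 ± 5.4 to 654 ± 32.3. Of the cAMP target genes, an intronic peak of the cAMP phosphodiesterase gene Pde4d (chromosome 13:109821677–109823366) rose from 514 ± 64.2 to 1520 ± 95.5, the Fosl2 promoter, of an AP-1 subunit, rose by 1.36 ± 0.11, and an intronic peak of Crem, a cAMP-responsive repressor (chromosome 18:3280500–3282077), rose by 0.69 ± 0.11. The promoter of the chemokine gene Ccl3 (chromosome 11:83646107–83649993) fell by 1.14 on the log2 scale, from 1230 ± 106 to 557 ± 46.7, and the Ccl5 promoter fell by 0.55 (limma adjusted p = 0.0052).

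With limma, 5740 of 38525 tested peaks (14.9%) changed with PGE2 in resting WT cells, 4186 more and 1554 less accessible. The largest rise among peaks named by the fixed rule was in an intron of Myo16, an unconventional myosin (3.58 ± 0.33, from 21 ± 5.32 to 258 ± 31.5), and rises of 2.77 to 3.31 were seen at Uchl5, Klc1, Rgs1 and Rnf125. Falls were smaller, the largest being −1.26 ± 0.25 at a distal peak of the calcium sensor gene Ncald and −1.22 ± 0.16 in an intron of Gnas, which encodes the stimulatory G protein subunit through which EP2 and EP4 raise cAMP (554 ± 63.7 to 237 ± 31.1). The opened peaks were distal, with promoters making up 6.33% of them against 31.3% of tested peaks. Fold changes are on the log2(count + 1) scale and understate the change of low peaks.

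Resting WT cells given PGE2 also changed at single peaks of receptor, migration and transcription factor genes. The promoter of Tigit, an inhibitory receptor (chromosome 16:43663747–43665296), rose from 995 ± 56.2 to 1790 ± 21.8, and an exon peak of Havcr2, encoding the inhibitory receptor TIM-3, rose by 1.30 ± 0.18. The chemokine receptor gene Cxcr4 gained at a distal peak (chromosome 1:128712666–128713596), from 82.1 ± 10 to 239 ± 36.5. An exon peak of the TGF-β receptor gene Tgfbr2 rose by 1.35 ± 0.15, and an intronic peak of Tcf7, a transcription factor of early lymphocytes, by 1.46 ± 0.19. Id2, a repressor that NK cells need, fell at a distal peak (chromosome 12:25092256–25093723) from 1540 ± 94.2 to 967 ± 79.3. The Gzmb promoter, of the cytotoxic protease granzyme B in a family of similar genes, rose from 509 ± 41.8 to 831 ± 69.7.

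Of 18 fixed gene lists, the cAMP and CREB target list had 50 peaks up and 12 down of 225, and 55 and 12 adjusted over the list alone. Its camera test gave adjusted p = 0.0178, and adjusted p = 0.315 with an estimated correlation. The migration list had 24 up and 5 down of 118 peaks, or 29 and 6 adjusted over the list alone (camera adjusted p = 0.0426, and adjusted p = 0.518 with an estimated correlation). NK receptor genes had 18 up and 31 down of 131, or 21 and 45 adjusted over the list alone, the fallers including distal Klra7, of a receptor family with uncertain assignment (camera adjusted p = 0.0247, and adjusted p = 0.518 with an estimated correlation). The list of ILC2 and ILC3 markers, innate lymphoid genes such as Kit and Il1rl1, had 8 up and 1 down of 27, or 11 and 4 adjusted over the list alone (camera adjusted p = 0.0247, and adjusted p = 0.447 with an estimated correlation).

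The other lists passed no camera test in this comparison. NK cytokine and chemokine genes had 21 peaks up and 17 down of 109, cytotoxic granule genes 11 and 4 of 68, receptor activation genes 33 and 14 of 201, and IL-2, IL-15 and STAT5 genes 23 and 4 of 111. NK transcription factor genes had 30 up and 11 down of 211, TGF-β and tissue residency genes 17 and 3 of 105, glycolysis and mTOR genes 11 and 0 of 70, interferon-stimulated genes 3 and 0 of 30, and prostanoid receptor genes 2 and 2 of 33. Among the reference and marker lists, housekeeping genes had 3 up and 4 down of 43, B cell markers 1 and 4 of 18, T cell markers 10 and 3 of 32, myeloid markers 1 and 0 of 10, and erythroid markers 0 of 4 peaks. Adjusted over the list alone, these 14 lists gave 24 and 18, 11 and 4, 37 and 16, 23 and 5, 34 and 13, 21 and 8, 11 and 0, 3 and 0, 2 and 1, 3 and 4, 1 and 4, 10 and 5, 1 and 0, and 0 peaks, in the same order.

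**Figure D2:**
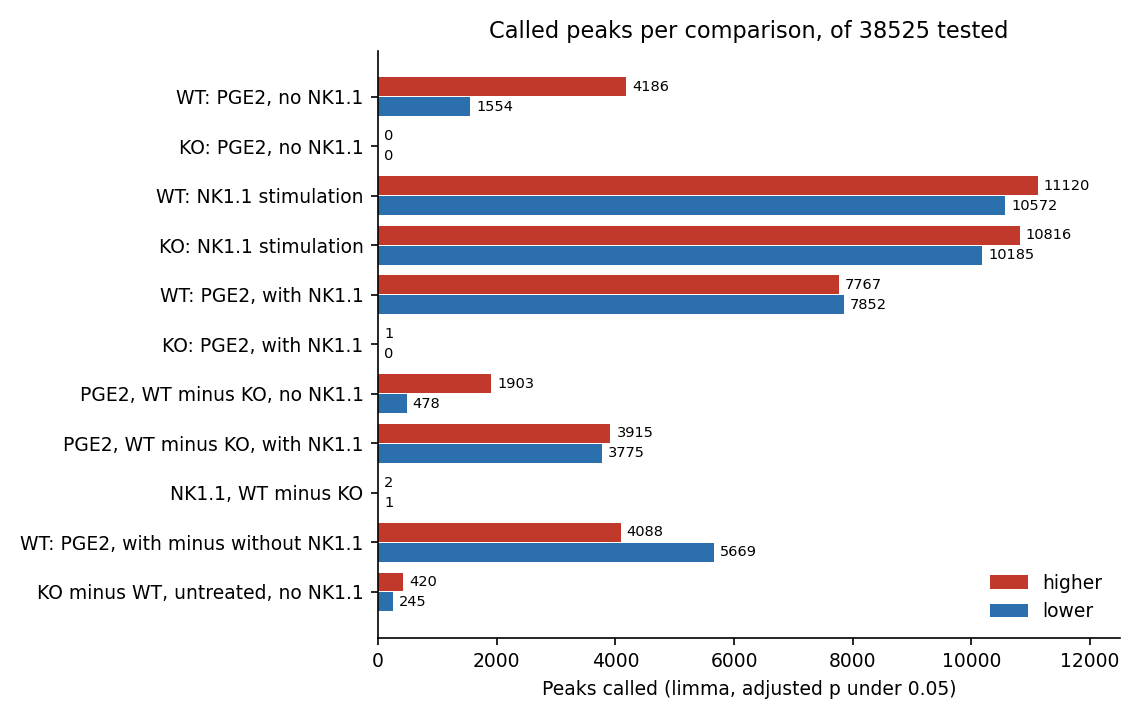
Peaks called with limma in each of 11 comparisons, drawn as bars from 0 (red more accessible, blue less accessible). PGE2 alone called 5740 peaks in WT and 0 in the KO.

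In resting KO cells, PGE2 gave smaller differences at the genes it had opened in WT. The Pdcd1 peak differed by 0.41 between PGE2 and untreated KO cells, and the Stat3 peak by 0.30. The Pde4d peak was 460 ± 18.6 without and 560 ± 49.2 with PGE2, and the Tigit promoter was 840 ± 30.7 and 1000 ± 99.8. The difference between the genotypes was itself called at the peaks of Pdcd1 (2.99, limma adjusted p = 1.3e-07), Stat3 (2.44, limma adjusted p = 2.3e-11), Pde4d (1.29, limma adjusted p = 2.7e-08), Nt5e (2.41, limma adjusted p = 3.1e-05), Tigit (0.60, limma adjusted p = 0.00044) and Crem (0.53, limma adjusted p = 0.026).

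With limma, 0 peaks passed the threshold for PGE2 in resting KO cells, 1520 had an unadjusted p under 0.05 (3.95% of those tested), and edgeR and DESeq2 also called 0, with 1245 and 1267 at an unadjusted p under 0.05. Without replicate 3 of the resting KO with PGE2 limma called 2 peaks, and with the libraries numbered 1 and 2 alone, an alternative added later with 1 untreated library, it called 272. That untreated library, replicate 2, stood apart from all others on principal component 5 (51.74, others −14.89 to 9.16). With all libraries, all 18 gene lists had 0 called peaks, also adjusted over the list alone. The migration list passed camera (adjusted p = 0.0261), and had adjusted p = 0.704 with an estimated correlation. The PGE2 effect differed between the genotypes at 2381 peaks, 1903 with a more positive and 478 with a more negative effect in WT. In that test 31 peaks of cAMP and CREB target genes were more positive and 6 more negative (camera adjusted p = 0.168, and adjusted p = 0.688 with an estimated correlation), and NK receptor genes were lower (11 and 18 peaks, camera adjusted p = 0.00671, and adjusted p = 0.688 with an estimated correlation). Of the 4186 peaks that PGE2 opened in WT, 63.8% were higher with PGE2 in the KO, against 52.2% of all tested peaks, with a median log2 change of 0.06 (camera p = 0.000203, and p = 0.282 with an estimated correlation). In simulated data for this comparison, 82% of 50 peaks changed 2-fold, 52% of 50 changed 1.5-fold and 8% of 50 with the smallest simulated change were recovered. With as few changed peaks as simulated, most changes well below 1.5-fold would thus not have been called. A change as broad as that in WT was not simulated.

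Stimulation through NK1.1 opened cytokine and chemokine genes in WT cells. An exon peak of Xcl1, a chemokine that recruits dendritic cells (chromosome 1:164928927–164932073), rose from 43 ± 13.5 to 2620 ± 766, a log2 change of 5.90 ± 0.28 (limma adjusted p = 1.27e-19). An exon peak of Tnfrsf9, the co-stimulatory receptor 4-1BB (chromosome 4:150944646–150947517), rose from 33 ± 3.47 to 741 ± 86.1. The Ifng promoter, of the main NK cytokine (chromosome 10:118440476–118441519), rose from 389 ± 32.6 to 812 ± 69.2, and the promoter of the nuclear receptor gene Nr4a1 by 1.98. Cish, a feedback inhibitor of IL-15 signalling, rose at a distal peak (chromosome 9:107312631–107313754) from 225 ± 5.43 to 871 ± 49.2. Of the peaks named by rule, the promoter of Dohh, an enzyme of translation factor maturation, had the largest fall (−2.33 ± 0.18, from 254 ± 32.3 to 49.6 ± 4.75), next to an intron of Thada (−2.33 ± 0.17).

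With limma, 21692 peaks changed with stimulation in WT (11120 more and 10572 less accessible) and 21001 in the KO (10816 and 10185). Rises of 4.92 to 5.34 were seen in WT at Ccl1, in a family with uncertain assignment, and at Rgs1, Scyl2, Eea1, Tagap and Tnfaip3, which encodes a brake on NF-κB. In the KO, Xcl1 rose by 5.78 ± 0.31, an intron of the IL-2 receptor gene Il2ra by 5.21 ± 0.47, the Tnfrsf9 exon by 4.42 ± 0.17 and the Cish peak by 2.29 ± 0.10. An intron of the chemokine receptor gene Cx3cr1 rose by 1.81 ± 0.08 in WT and 1.79 ± 0.09 in the KO, and a distal peak of Tbx21, which encodes T-bet, by 1.57 ± 0.09 and 1.56 ± 0.09. Kit, of a receptor of progenitor cells, fell at a distal peak by 1.58 in WT and by 1.28 in the KO.

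NK cytokine and chemokine genes had 81 of 109 peaks up and 9 down with stimulation in WT, and 83 and 10 adjusted over the list alone (camera adjusted p = 6.07e-17, and adjusted p = 0.00616 with an estimated correlation). Receptor activation genes had 142 up and 23 down of 201 in WT (camera adjusted p = 8.98e-15, and adjusted p = 0.0106 with an estimated correlation). In the KO these 2 lists had 82 up and 7 down, and 139 up and 23 down. The IL-2, IL-15 and STAT5 list had 67 up and 20 down in WT (camera adjusted p = 8.28e-05, and adjusted p = 0.0834 with an estimated correlation) and 70 up and 18 down in the KO (adjusted p = 1.14e-06, and adjusted p = 0.0247 with an estimated correlation). Cytotoxic granule genes had 36 up and 11 down in WT (adjusted p = 0.00131, and adjusted p = 0.101 with an estimated correlation). For cAMP and CREB targets the counts were 102 up and 51 down (adjusted p = 0.00918, and adjusted p = 0.101 with an estimated correlation), and for myeloid markers 6 up and 0 down (adjusted p = 0.0284, and adjusted p = 0.178 with an estimated correlation). In the KO the last 3 lists, in this order, gave adjusted p = 0.000233, 0.00948 and 0.00948, and adjusted p = 0.0634, 0.1 and 0.1 with an estimated correlation. NK receptor genes changed both ways, with 39 up and 57 down in WT and 41 and 45 in the KO (camera adjusted p = 0.302 and 0.809), as did NK transcription factor genes, with 80 and 67, and 74 and 60 (adjusted p = 0.74 and 0.518).

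The stimulation response was shared between the genotypes. Of the 10816 peaks opened in the KO, 99.3% also lay higher in WT and 9789 (90.5%) were called there, and of the 10185 closed in the KO, 8452 (83%) were called lower in WT. The response differed between the genotypes at 3 peaks, all on chromosomes 14 and 15 and named here after their values were seen. They were a distal peak of Dad1 (chromosome 14:53802254–53803069, −1.60), one of Abhd4 (chromosome 14:54271948–54273005, 1.85) and one of Ywhaz (chromosome 15:36818620–36820540, 1.40). At an unadjusted p under 0.05 there were 1452 such peaks, and edgeR and DESeq2 each called 4. Camera passed the NK receptor list (adjusted p = 0.0349, and adjusted p = 0.783 with an estimated correlation) and the IL-2, IL-15 and STAT5 list (adjusted p = 0.0149, and adjusted p = 0.569 with an estimated correlation), each with 0 called peaks.

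PGE2 during stimulation lowered the same cytokine and activation genes in WT cells. The Ifng promoter was 812 ± 69.2 after stimulation alone and 438 ± 22.1 with PGE2, a fall of −0.89 ± 0.09 (limma adjusted p = 1.13e-09), with no overlap between the 4 libraries of each group. The Xcl1 promoter fell from 1680 to 856, and a distal Xcl1 peak (chromosome 1:164989659–164990590) from 353 ± 37.2 to 33.4 ± 3.55. The chemokine gene Ccl1, in a family with uncertain assignment, showed the largest fall among peaks named by rule, at an exon (chromosome 11:82173321–82177520, 2910 ± 1080 to 209 ± 53.2, −3.76 ± 0.22). A peak of Prf1, the pore-forming perforin (chromosome 10:61305846–61309038), fell from 709 ± 60.4 to 336 ± 18.2, and the Cish peak from 871 ± 49.2 to 352 ± 36.4. Tbx21 fell at a distal peak (chromosome 11:97124474–97125284) from 343 ± 39.3 to 118 ± 24.2, and one of Gata3, a lymphoid transcription factor, from 164 ± 28.9 to 37.4 ± 6.16.

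**Figure D3:**
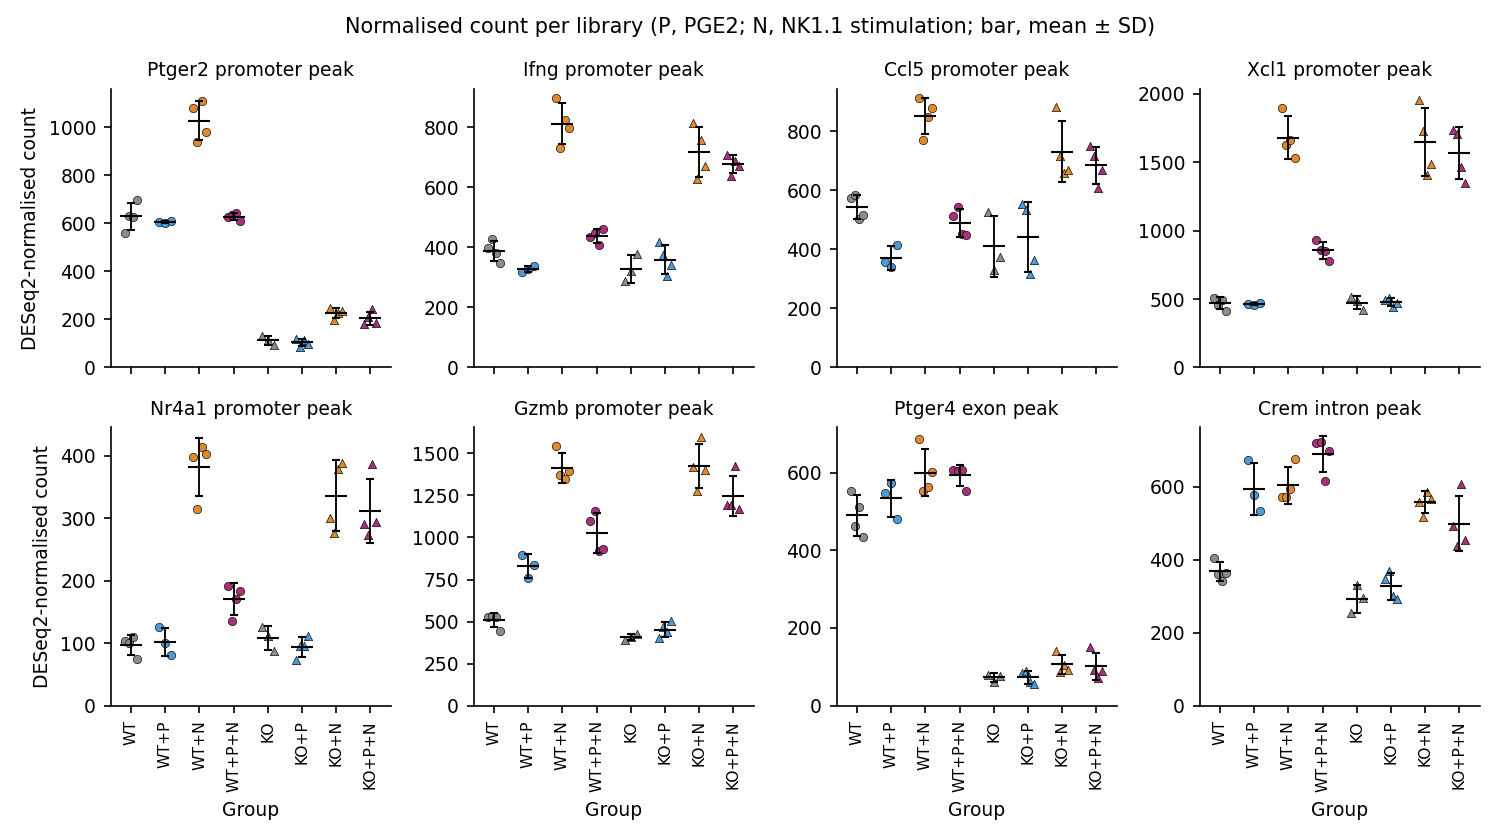
Normalised read counts at fixed peaks in the 8 groups (P PGE2, N NK1.1 stimulation), with points for libraries and bars for mean ± SD. The Ifng promoter averages 812 in stimulated WT, 438 in stimulated WT with PGE2 and 677 in stimulated KO with PGE2.

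PGE2 raised other genes in the same stimulated WT cells. The Pdcd1 peak rose from 161 ± 33.5 to 873 ± 265 (2.41 ± 0.22, limma adjusted p = 3.82e-11), the Tigit promoter from 1040 ± 40.4 to 1930 ± 77.2, the Pde4d peak from 561 ± 41.2 to 1330 ± 138, and Nt5e from 39.9 ± 8.23 to 152 ± 24.5. A distal peak of Cxcr4 (chromosome 1:128704760–128705831) rose from 155 ± 29 to 474 ± 70.7, one of Kit (chromosome 5:75779623–75781564) from 480 ± 35 to 1110 ± 90, and an intron of Lef1, a partner of Tcf7, from 282 ± 26.5 to 585 ± 16.9. The largest rises by the same rule were at Uchl5 (2.92 ± 0.24), at Csf2rb2, a cytokine receptor subunit (2.86 ± 0.36), at Zfp169 and E230016M11Rik (2.70 and 2.68), and at Rnf125, Prim2, 4933406G16Rik and Rptor (2.64 to 2.65).

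With limma, 15619 peaks changed with PGE2 in stimulated WT cells, 7767 more and 7852 less accessible. Promoters were 11% of the former and 30.6% of the latter. NK cytokine and chemokine genes had 13 peaks up and 70 down, 14 and 73 adjusted over the list alone (camera adjusted p = 7.9e-15, and adjusted p = 0.0121 with an estimated correlation). Receptor activation genes had 17 up and 107 down (camera adjusted p = 4.37e-11, and adjusted p = 0.0366 with an estimated correlation). Cytotoxic granule genes had 12 up and 34 down (camera adjusted p = 0.00084, and adjusted p = 0.114 with an estimated correlation), and IL-2, IL-15 and STAT5 genes 22 up and 44 down (camera adjusted p = 0.0143, and adjusted p = 0.271 with an estimated correlation). The migration list rose, with 49 up and 18 down (camera adjusted p = 0.0039, and adjusted p = 0.176 with an estimated correlation), as did T cell markers such as Lef1 (15 and 4, adjusted p = 0.0173, and adjusted p = 0.114 with an estimated correlation). Housekeeping genes such as Actb had 4 up and 15 down (adjusted p = 0.0236, and adjusted p = 0.285 with an estimated correlation). Peaks of cAMP and CREB target genes split evenly, with 62 up and 60 down, Pde4d rising and a distal peak of Junb, an AP-1 subunit, falling (−1.55 ± 0.10).

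In stimulated KO cells, cytokine genes differed less between PGE2 and untreated libraries. The Ifng promoter was 718 ± 83.6 without and 677 ± 29.2 with PGE2, a difference of −0.08 (limma adjusted p = 0.999). The Xcl1 promoter was 1650 and 1570, and the Cish peak 995 ± 83.8 and 849 ± 89.4. The PGE2 effect differed between the genotypes at the promoters of Ifng (−0.81, limma adjusted p = 2.4e-05), Xcl1 (−0.90, limma adjusted p = 4.6e-06), Ccl5 (−0.71, limma adjusted p = 0.0056), Nr4a1 (−1.06, limma adjusted p = 0.00054) and Ptger2 (−0.55, limma adjusted p = 0.0074), and at the peaks of Pdcd1 (2.14, limma adjusted p = 3.7e-06) and Pde4d (0.93, limma adjusted p = 5.8e-07). It was not called at the Gzmb promoter (−0.27, limma adjusted p = 0.12).

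With limma, 1 peak changed with PGE2 in stimulated KO cells, and 1634 had an unadjusted p under 0.05 (4.24%). It lies in an intron of Prim2, a DNA primase subunit (chromosome 1:33578273–33579139), and rose from 42.3 ± 4.08 to 87.4 ± 27.3 (0.98 ± 0.17, adjusted p = 0.0381), against a rise from 58.3 ± 15 to 362 ± 22.1 in WT. This call rests on single libraries, since limma called 0 peaks without any one of untreated replicates 1 to 4 or PGE2 replicates 1 and 2 (1053 to 1956 at an unadjusted p under 0.05), and 4 without PGE2 replicate 3. edgeR called 0 peaks (1382 at an unadjusted p under 0.05) and DESeq2 1. All 18 lists had 0 called peaks, with 1 receptor activation peak adjusted over the list alone, and camera passed the cytokine list (adjusted p = 0.000778, and adjusted p = 0.576 with an estimated correlation). In simulated data for this comparison, 84% of 50 peaks changed 2-fold and 50% of 50 changed 1.5-fold were recovered.

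The PGE2 effect in stimulated cells differed between the genotypes at 7690 peaks, 3915 more positive and 3775 more negative in WT. Cytokine and chemokine genes had 6 more positive and 57 more negative peaks (camera adjusted p = 6.14e-15, and adjusted p = 0.0117 with an estimated correlation). Receptor activation genes had 10 and 84 (camera adjusted p = 6.78e-12, and adjusted p = 0.0275 with an estimated correlation). The cytotoxic granule, IL-2 with STAT5, migration, housekeeping and T cell lists also passed camera, with adjusted p = 0.00274, 0.0178, 0.0179, 0.0205 and 0.0178, and adjusted p = 0.139, 0.27, 0.27, 0.27 and 0.13 with an estimated correlation.

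In WT cells the PGE2 effect also differed between stimulated and resting cells, at 9757 peaks, 4088 more positive and 5669 more negative with stimulation. At the Xcl1 promoter the difference was −0.95 (limma adjusted p = 3.2e-06) and at the Stat3 peak −2.15 (limma adjusted p = 1e-10), where PGE2 and stimulation each opened the same site. At the Tigit promoter it was 0.04 (limma adjusted p = 0.81). Cytokine genes had 6 more positive and 60 more negative peaks (camera adjusted p = 3.83e-15, and adjusted p = 0.0109 with an estimated correlation), and receptor activation genes 13 and 102 (camera adjusted p = 1.53e-12, and adjusted p = 0.022 with an estimated correlation). The cytotoxic granule, IL-2 with STAT5 and cAMP lists had adjusted p = 0.000369, 0.000239 and 0.0292, and adjusted p = 0.0869, 0.0869 and 0.183 with an estimated correlation. Of the 198 tests of a list in a comparison, 41 passed camera and 11 with an estimated correlation, which were the cytokine and receptor activation lists in both stimulation comparisons, in stimulated WT with PGE2 and in the 2 interactions that contain it, and the IL-2 with STAT5 list in KO stimulation.

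Peak sets called in one comparison were read in comparisons that share no library with it. Over the 10816 peaks opened by stimulation in the KO, 6148 (56.8%) were called lower and 742 higher with PGE2 in stimulated WT, with a median of −0.41 (camera p = 0.000134 with an estimated correlation). Over the 10185 peaks closed by stimulation in the KO, 4735 (46.5%) were called higher and 54 lower, with a median of 0.30. Among the former peaks, the median change with stimulation in WT was 0.99 without and 0.39 with PGE2, and among the latter −0.57 and −0.18. PGE2 alone raised the mean log2 value over the former peaks in resting WT, from 6.59 to 6.82 (exact permutation p = 0.0286). Part of their smaller change with PGE2 thus reflects a higher level before stimulation. The mean log2 value over the former set was 7.83 ± 0.07 in stimulated WT and 7.36 ± 0.04 with PGE2 (difference −0.48, exact permutation p = 0.0286, the smallest that 4 against 4 libraries allow, adjusted p = 0.0497). The adjustment also covered sets tested in the comparisons that had called them, whose outcome was fixed in advance. This adjusted p therefore does not show a pass at 0.05. In the KO, where the untreated libraries had also served to call this set, the mean was 7.94 ± 0.08 and 7.86 ± 0.13 (exact permutation p = 0.343, adjusted p = 0.429). Compared by replicate number, it was lower with PGE2 in all 4 pairs of these KO libraries (−0.149 to −0.013, exact sign-flip p = 0.125, the smallest for 4 pairs).

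**Figure D4:**
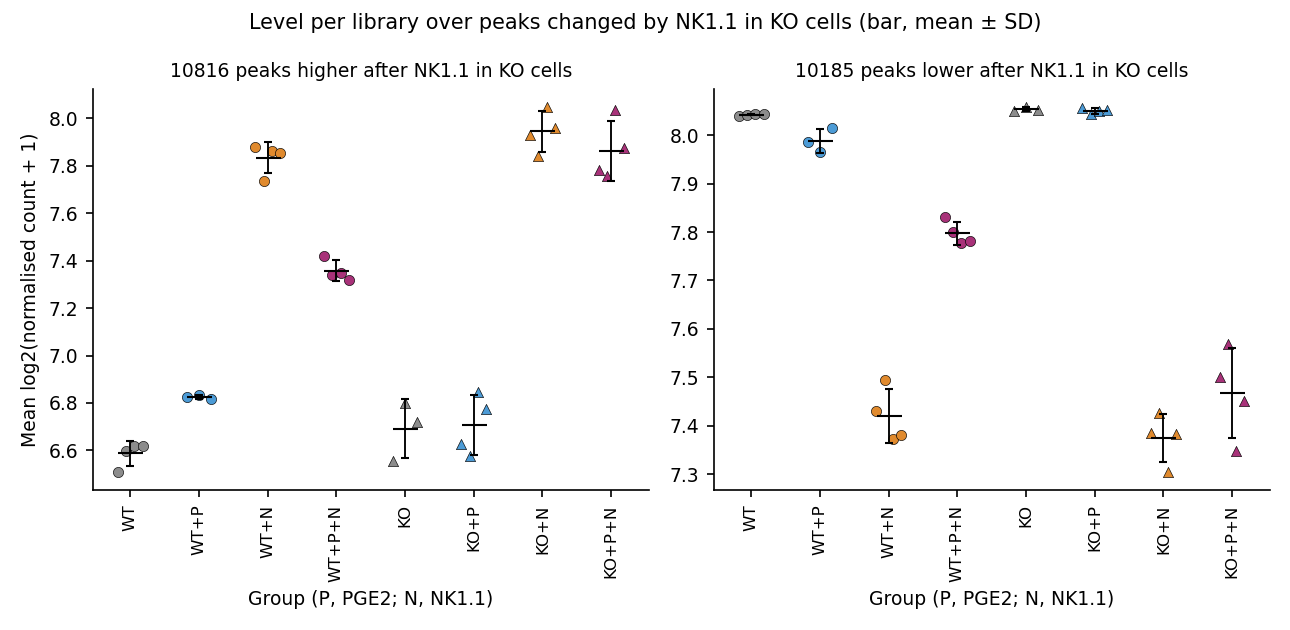
Mean log2(normalised count + 1) per library over the 10816 peaks higher and the 10185 peaks lower after NK1.1 stimulation in the KO, by group. Stimulated WT libraries with PGE2 average 7.36 over the former set, between resting (6.59) and stimulated WT (7.83).

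The peaks that PGE2 opened in resting WT cells overlapped with those of stimulation. Of these 4186 peaks, which include the Stat3 and Pdcd1 sites, 2472 (59.1%) were also called higher with stimulation in the KO and 552 (13.2%) lower, where the shares over all tested peaks give 1175 and 1107 (camera p = 0.0308 with an estimated correlation). Of the 1554 closed peaks, 712 (45.8%) were called lower and 365 (23.5%) higher, against 410.8 and 436.3 (camera p = 0.267 with an estimated correlation). Both readings were chosen after the data were seen. In stimulated WT, 2132 (50.9%) of the opened peaks were again called higher with PGE2 and 497 lower, against 843.9 and 853.2 (camera p = 0.0218 with an estimated correlation). In stimulated KO, 49.7% lay higher with PGE2 and 1 was called. Of the closed peaks, 550 (35.4%) were again called lower with PGE2 in stimulated WT, against 316.7, 45% lay lower with PGE2 in resting KO and 49.5% in stimulated KO.

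Without PGE2 or stimulation, the genotypes differed at single peaks of Lag3, Ncr1, Il18r1 and Pgk1. A distal peak of the inhibitory receptor gene Lag3 (chromosome 6:124900861–124902342) was higher in the KO, 265 ± 33.9 against 159 ± 5.84 (0.72 ± 0.13, limma adjusted p = 9e-04). The promoter of Ncr1, the activating receptor NKp46 (chromosome 7:4337228–4340115), was lower, 1440 ± 102 against 1900 ± 119 (limma adjusted p = 0.0247), as was that of Il18r1, an IL-18 receptor subunit, 606 ± 14.5 against 799 ± 34.3. The promoter of the glycolytic gene Pgk1 (chromosome X:106186495–106188337) was higher, 1330 ± 129 against 600 ± 45.8 (1.14 ± 0.09, limma adjusted p = 2.49e-12).

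With limma, 665 peaks (1.73%) differed between the untreated resting genotypes, 420 higher and 245 lower in the KO. Most of the largest differences lay on chromosomes 14 and 15, which carry the targeted loci. On chromosome 15, a distal peak of the ribonucleotide reductase gene Rrm2b (chromosome 15:37874061–37874894) was 248 ± 22.2 in the KO and 10.1 ± 4.68 in WT (4.59 ± 0.34), and an exon of Trio 439 ± 56.6 and 37 ± 12.6. On chromosome 14, the promoter of Pnp2, a purine nucleoside phosphorylase, held 3 reads in 3 KO libraries and 656 in 4 WT libraries, a normalised ratio of 183 (exact 95% interval 62.5 to 892). A distal peak of Dad1 (chromosome 14:53943134–53943846) held 0 reads in the KO and 267 in WT, and was at least 74.6-fold lower in the KO, with a floor of 3 reads over the group. Chromosomes 14 and 15 held 205 of the 665 called peaks (30.8%) and 8.12% of tested peaks (odds ratio 5.33, 95% interval 4.48 to 6.32, Fisher's exact test, two-sided p = 5.73e-66). Of the 56 peaks that differed by 2 or more on the log2 scale, 50 lay there, 4 on chromosome 5, and 1 each on chromosomes 12 and Y. On chromosome 5, a distal peak of 5830416I19Rik (chromosome 5:64037851–64038661) was 9.66 ± 5.03 in the KO and 108 ± 11.6 in WT (−3.47 ± 0.32). That chromosome had 51 of 2411 tested peaks called (2.12%), and the cause was not tested.

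**Figure D5:**
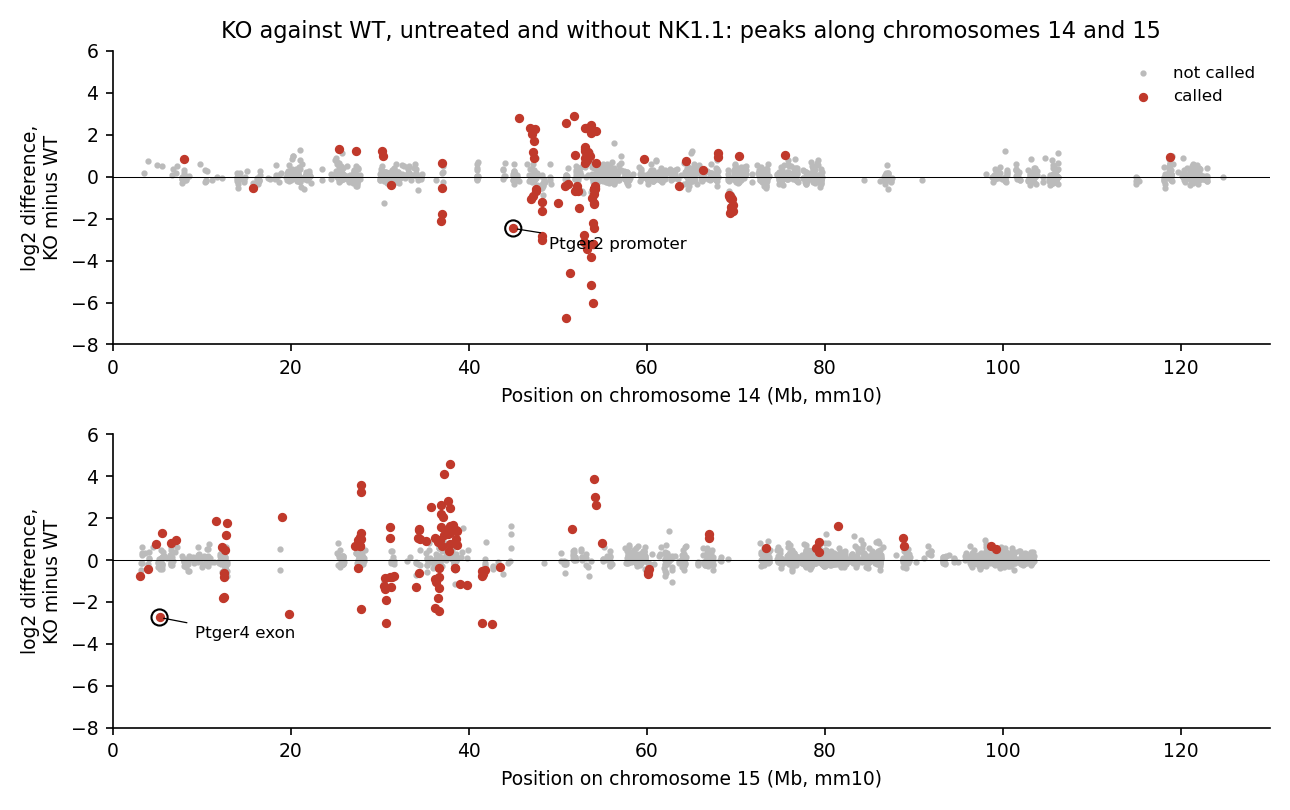
Log2 difference between KO and WT in untreated unstimulated cells along chromosomes 14 and 15 (position in Mb), 1 point per tested peak, called peaks in colour. On both chromosomes 205 of 3127 peaks are called, against 460 on all others, 1.3% of those tested there.

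NK receptor genes had 2 peaks higher and 4 lower in the KO, 4 and 16 adjusted over the list alone (camera adjusted p = 0.00875, and adjusted p = 0.481 with an estimated correlation), and no other list passed camera. NK cytokine and chemokine genes had 4 higher and 2 lower of 109, 12 and 10 adjusted over the list alone (camera adjusted p = 0.91). Housekeeping genes had 4 higher and 0 lower, with the Pgk1 promoter and the distal Ywhaz peak among them, and NK transcription factor genes had 0 of 211 called. The count of 665 depended on the processing, with 307 peaks with quantile normalization, 1016 with a replicate block across groups and 1058 with DESeq2. Of the called peaks 63.2% were higher in the KO, 76.9% with total-sum scaling, 52.1% with quantile normalization and 45.7% with only the libraries compared. The count also depended on single libraries. It was 245 without replicate 3, 378 without replicate 4 and 851 without replicate 2 of the untreated resting KO, and 330 and 390 without replicates 1 and 2 of the matching WT. In the other conditions 5566 peaks differed between the genotypes in resting cells with PGE2, 279 in stimulated untreated cells, and 15468 in stimulated cells with PGE2.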

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

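The tests of strain DNA, of a share of cells that did not respond, of PGE2 acting through EP2 and EP4, of compression as the whole cause, of a batch, and of the peaks outside chromosomes 14 and 15 alone were chosen only after the results were seen, and the bounds by which the test of lost EP2/EP4 signalling was read were changed after its values were seen.

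Peaks on the chromosomes of the targeted loci differed most between the genotypes. In the KO the Pnp2 promoter and a distal peak assigned to Dad1 held almost no reads, and peaks of Rrm2b and Trio were higher. Missing reads can mean closed chromatin or sequence that is absent or did not align, and these were not told apart. The tables argue against DNA of another strain around the targeted alleles as the whole cause, since 69.2% of the 665 called peaks, among them those of Lag3, Ncr1 and Il18r1, lay on other chromosomes, 46.1% of 245 without KO replicate 3 to 76.9% of 851 without KO replicate 2 (53% of 330, 57.7% of 390 and 61.4% of 378 without WT replicates 1 and 2 and KO replicate 4), though only 258, and 40 without KO replicate 3, stayed called when adjusted over those chromosomes alone. For chromosomes 14 and 15 such DNA is a candidate explanation, since the odds ratio of a called peak lying there was 5.33, but no sequence was examined. Of these 205 peaks, 98.5% kept their sign in stimulated libraries, against 92.6% on the other chromosomes. Of them, 182 lay at 40 to 70 Mb of chromosome 14 or 0 to 70 Mb of chromosome 15, which hold Ptger2 and Ptger4. There 14.4% of 1260 tested peaks were called, against 1.3% on other chromosomes. These bounds were not set beforehand. PGE2 in stimulated WT moved 56.6% of these 205 peaks opposite to their difference in the KO, with a 95% interval of 49.5 to 63.5. By the bounds set before the values were seen, an interval holding 50 counted against loss of EP2/EP4 signalling. By the changed bounds such loss stays open for them, since the interval holds both 50 and 60. On the other chromosomes PGE2 moved 63.3% that way (interval 58.7 to 67.7), and 64.3% of the 258 (58.2 to 70.2). These intervals count peaks as independent, which they are not. Resting KO lay nearer to stimulated libraries on the first component (−75.7 against −94 in WT), and PGE2 lowered stimulation-opened peaks, so over 50% can arise otherwise. Lost signalling would lower peaks that PGE2 opened in resting WT. In stimulated untreated KO they lay 0.1 higher (exact permutation p = 0.2, adjusted p = 0.267), which decides nothing. The 0.18 in resting cells (exact permutation p = 0.0857) is biased upward, since the same WT libraries had called these peaks. Lost signalling stays open beside an unrecorded batch and GzmbCre.

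Cytokine genes such as Ifng, Xcl1 and Ccl1 lay between their resting and stimulated levels when WT cells met PGE2 during stimulation, as did the stimulation sets as a whole. A share of cells that did not respond would leave every stimulation-opened peak the same fraction of its rise, and the tables argue against it as the whole cause, since 26.6% of 1691 peaks lay over 2 standard errors from the median fraction of 28.5%, against 1.06% in the KO. Signal compressed by level in these libraries is argued against as the whole cause, since the log2 change with PGE2 of opened minus closed peaks of equal level in stimulated KO cells was a median of −0.75 over 10 bins of level (−0.96 to −0.41), but a part stays open, since, among 15885 peaks called by neither KO stimulation nor PGE2 in resting WT, the most accessible of 5 equal groups fell by 0.10 on the log2 scale against the least accessible, at the bound set. PGE2 acting through EP2 and EP4 is in line with a median fall of 0.068 in the KO over the peaks opened in WT, 16.5% of the 0.41 in WT over those opened in the KO (16.3% to 18.6% over 1 set of peaks in both), and remains a hypothesis. In 35 splits of the stimulated WT libraries, 1, the real one, called as many as 15619 peaks, and the highest other called 1. No other grouping of these libraries came near that total, which does not cover chance between animals or cultures.

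KO libraries numbered 1 and 2 differed from those numbered 3 and 4, with a mean correlation of deviations from the group means of 0.178 within and −0.176 across these number groups. Lower depth is argued against, since the gap between these correlations was 0.354 and stayed at 0.292 with all libraries thinned to the lowest depth. A batch stays open, since no label gives one and the gap in WT was 21.1% of that in the KO, and no biological explanation was tested.

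Other splits of the same libraries set these results against chance. For the genotypes, 1 of 35 splits, the real one, called as many as the 665 peaks, and the highest other, which moves only WT replicate 4 to the KO side, called 221. No other split reached this count, which includes Pnp2 and Lag3. Splits judge the total over these libraries, not a single peak and not chance between animals or cultures. For PGE2 in resting KO the splits decide nothing, since any of the 35 reaches a count of 0, and the split of numbers 1 and 2 against 3 and 4, the highest, called 2908. For PGE2 in stimulated KO, 7 of 35 splits called at least as many as the 1 peak at Prim2, and the same division called 5524, so the splits point to the structure by number. They compare totals and cannot judge the Prim2 peak itself, for which chance stays open. That peak was also among those PGE2 opened in resting WT, and rose by 2.65 with PGE2 in stimulated WT (limma adjusted p = 6.49e-15). In the KO libraries numbered 3 and 4 alone limma called 0 peaks for PGE2 in resting and in stimulated cells (1128 and 1060 at an unadjusted p under 0.05), and in those numbered 1 and 2 alone 272 and 16. The 1 untreated resting library of the latter, replicate 2, was assumed to vary like the other groups. It stood apart on principal component 5, with 1.5% of the variance, at 51.74, where all other libraries lay between −14.89 and 9.16. It held 9241985 reads in peaks, against 20097949 and 17684832 in replicates 3 and 4 of its group, and the most peaks at 0 reads, 26. The resting calls within numbers 1 and 2 therefore rest on a library that stood apart.

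Effects differed between the groups, by tests of the difference itself, at 2381 peaks for PGE2 between genotypes in resting cells, 7690 in stimulated cells, 3 for stimulation between genotypes, and 9757 for PGE2 between stimulated and resting WT. Of 100 splits drawn for each, 3 called as many as the 2381, with a highest other of 3732, and 3 as many as the 7690, with a highest other of 10029. For the 9757 only the real split, 1 of 100, did so, with a highest other of 7957. The draws regrouped libraries within each state, so a draw could keep a real difference in 1 state and lose it in the other. They are thus no clean measure of chance for an interaction. For the 2381 and the 7690, regrouped libraries called more peaks than the real groups, and chance is not excluded by the splits. For the 3 peaks at Dad1, Abhd4 and Ywhaz, 6 of 100 splits called as many, up to 694, and chance cannot be excluded.

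Single libraries stood apart from the other 3 of their group in 12 of 216 groups tested, and chance gives this in about 1 in 20 groups. Replicate 2 of stimulated untreated WT had 72 on the first principal component (others 89.9 to 91.7), a mean of 7.736 over the stimulation-opened set (7.855 to 7.878) and 314 at the Nr4a1 promoter (398 to 415). Replicate 4 of resting untreated WT had 447 at the Gzmb promoter (528 to 534), 27.5 at the Ccl1 intron (13.6 to 14.7) and 283 at the Thada intron (244 to 250). Replicate 1 of that group had a mean of 8.04 over the stimulation-closed set (8.042 to 8.043). In stimulated KO with PGE2, replicate 2 had 0.882% of its reads in the top peak (0.601 to 0.636) and replicate 3 had 1430 at the Gzmb promoter (1170 to 1200). In stimulated WT with PGE2, replicate 4 had 553 at the Ptger4 exon (604 to 607) and replicate 1 had 311 at the Rnf125 intron (219 to 225). Replicate 3 of stimulated untreated WT had 42.8 at the Hp1bp3 intron (18.2 to 21.7).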

How the results depend on the processing

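The comparisons within libraries 1 and 2 or 3 and 4, the term for these number groups, promoter peaks only, the omission of chromosomes 14 and 15, and the differences by number were chosen only after the results were seen. No called peak of a named gene changed sign under any alternative run. Of named and called peaks over all settings, 84 fell short of the threshold and 1550 kept it for PGE2 in resting WT, 44 and 2376 for PGE2 in stimulated WT, 33 and 2567 for WT stimulation, 28 and 2480 for KO stimulation, 9 and 11 for PGE2 in stimulated KO, and 180 and 648 for the genotypes.

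With a log2 change of at least 1 required, which by construction calls fewer peaks, counts were 1314 for PGE2 in resting WT, 7181 and 7086 for stimulation in WT and the KO, 3282 and 0 for PGE2 in stimulated WT and KO, 1013 and 2391 for the genotype interactions with PGE2 in resting and stimulated cells, 3320 for PGE2 by stimulation, and 223 for the genotypes. Libraries 1 and 2 alone, which hold only 1 library of resting WT with PGE2 and 1 of untreated resting KO, gave 2545 for PGE2 in resting WT, 272 and 16 for PGE2 in resting and stimulated KO, 864 and 3484 for the genotype interactions with PGE2, 74 for genotype by stimulation, and 4028 for PGE2 by stimulation. Of the 262 peaks higher in resting KO there, 52 (19.8%) were among the peaks PGE2 opened in WT, which are 10.9% of tested peaks, and 130 (49.6%) among those stimulation opened in WT, which are 28.9%. The 1 untreated resting KO library behind these calls, replicate 2, stood apart on principal component 5 (51.74, others −14.89 to 9.16). Libraries 3 and 4 alone gave 0 for PGE2 in stimulated KO and 1651 for the genotypes.

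PGE2 in stimulated KO, at Prim2, gave 0 peaks with edgeR and with limma on only the libraries compared (1382 and 971 at an unadjusted p under 0.05), and 3 with a replicate block within genotype. Genotype by stimulation gave 5 with that block and 5 with a term for the number groups. The genotypes gave 307 with quantile normalization, 1016 with a replicate block across groups, 1058 with DESeq2, and 258 without chromosomes 14 and 15. The cause was not tested. The block moved no other count by over 1.5 times. Same-numbered libraries did not pair by the rule set, with 24 of 42 pairs over a correlation of 0.1 (lowest −0.005), though 27 of 30 libraries correlated best with their own number. Chromosome Y signal also followed the number within genotype, so the unpaired tests may ignore a shared source of cells. Compared by number, the mean over peaks that stimulation opened in WT was lower with PGE2 in all 4 pairs of stimulated KO libraries (−0.132 to −0.008, exact sign-flip p = 0.125, the smallest for 4 pairs). The mean over peaks that PGE2 opened in resting WT was higher with PGE2 in all 3 pairs of resting KO libraries (0.058 to 0.083, exact sign-flip p = 0.25, the smallest for 3 pairs), so a small effect of PGE2 in the KO stays open.

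Without each library in turn, PGE2 in stimulated KO gave 0 to 4 peaks, 4 without replicate 3 of the PGE2 group and 0 without any one of its replicates 1 and 2 or untreated replicates 1 to 4. PGE2 in resting KO gave 0 to 2, with 2 without replicate 3 of the PGE2 group. The genotypes gave 245 without KO replicate 3 to 851 without KO replicate 2, with 378 without KO replicate 4 and 330 and 390 without WT replicates 1 and 2. All other counts stayed within 1.5 times, such as 4178 to 5319 for PGE2 in resting WT and 13866 to 14916 in stimulated WT.

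Gene lists passed camera 41 times, and 11 with an estimated correlation. With promoter peaks only, the migration and ILC lists in resting WT with PGE2 pointed down (adjusted p = 0.601 and 0.964). Of peaks PGE2 closed in resting WT, 45% lay lower with PGE2 in resting KO, and 52.1% with quantile normalization and 51.2% with the block. In KO stimulation 62.8% lay lower, also 62.8% with quantile normalization, where camera lost its call. The cause was not tested. Quantile normalization shifted the median by −0.115 and −0.134 in WT and KO stimulation and moved the share of calls that rose from 51.3% to 41.2% and from 51.5% to 40.7%. For the genotypes that share was 63.2%, 76.9% with total-sum scaling and 52.1% with quantile normalization. The planned limit to peaks within 10 kb of a start site and the motif alternatives were not run. In simulated data 48% to 54% of peaks changed 1.5-fold were recovered, and depth was not varied there. Depth limited what could be said of the Dad1 peak with 0 reads in the KO to at least 74.6-fold.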

Other observations

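The tests of retained rise by peak class, of the Pgk1 promoter and of chromosome Y peaks were chosen only after the results were seen, and the genes named in this part were chosen after their values were seen.

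PGE2 took away the stimulated opening of some genes nearly in full and spared others. At the promoter of Icam1, the adhesion molecule of NK contacts, stimulation of WT cells added 490 normalised counts without PGE2 and −47.1 with it, and at the promoter of Btg3, which restrains proliferation, 399 and −103. An intron of Itgae, the residency integrin CD103, gained 403 without and 490 with PGE2, and an intron of Inpp4b, a lipid phosphatase of the PI3K pathway, 448 and 439. Introns of Prkca, a protein kinase C, and Pik3ap1, a PI3K adaptor, retained 89.8% and 91% of their rise.

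The rise retained was read over 1691 peaks that gained at least 100 normalised counts with stimulation in WT. They were also called higher with stimulation in the KO, and changed little with PGE2 in resting WT. Of these, 556 promoters retained a median of 23.9% of the rise with PGE2 and 1135 other peaks 30.9% (permutation p = 0.00001, the smallest that 100000 permutations give). Promoters and other peaks were not matched for level, so an effect of level on this difference stays open. Of the 185 peaks that retained under 10%, 113 (61.1%) were promoters, and of the 109 that retained over 60%, 15 (13.8%) were. Peaks are not independent replicates, so this p-value describes these libraries.

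Pgk1, a glycolytic gene also in the housekeeping list, was higher in the KO at its promoter under all 4 conditions, by 1.14 on the log2 scale in untreated resting cells, with a range of 0.24 between the lowest and highest difference. Its other peak was not called (−0.33, limma adjusted p = 0.516, in untreated resting cells). A Pgk1 promoter carried by a targeting cassette may give such a constant gain, as a hypothesis, and the labels do not describe the alleles' construction.

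Chromosome Y peaks, 15 in all and 11 of them assigned to Gm47283 or Gm21860, differed between libraries of a group. Within genotype, the replicate number took up 94.2% of the variance within groups (permutation p = 1e-05, the smallest that 100000 permutations give, with 51% at the 95th percentile). A source of cells shared by libraries of 1 number may give this, as a hypothesis. Replicate 3 of resting WT with PGE2 was at 129% of its group mean, where replicate 3 of the other WT groups was at 95.4 to 97.7% and replicate 1 at 132 to 141%.

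For stimulation, 1 of 35 splits, the real one, called as many as the 21692 peaks in WT, with a highest other of 3754, and 1 of 35 as many as the 21001 in the KO, with a highest other of 16612, from a split that moves only stimulated replicate 2 to the resting side. For PGE2 in resting WT, 1 of 35 splits called as many as the 5740 peaks, and the highest other, which moves only untreated replicate 4, called 2729. No other split reached these totals, which hold the Xcl1, Tnfrsf9 and Pdcd1 peaks. The splits judge totals over these libraries, not single peaks or chance between animals or cultures.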
